A study of Mus musculus with 6 samples.

How the data were processed

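Total RNA from the cortex of E12.5 mouse embryos was measured on 6 Illumina mouse BeadChip arrays, in which each gene is read by 50-base probes carried on beads. Per the labels, 3 arrays came from embryos homozygous for a floxed BAF170 (Smarcc2) allele and carrying Emx1-Cre (cKO), and 3 from embryos with the floxed allele and no Cre, described as littermate controls. The background strain was C57BL/6, per the labels, and the RNA was amplified with a NuGEN Ovation kit and labelled with biotin.

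The probe signals are intensity values as deposited: the mean brightness of the beads of each probe, not normalised and with the optical background still present, per the file headers and the values. The standard error of the beads is on the same intensity scale, and the number of beads stands beside it, per the file headers. Each probe also has a detection p-value against negative control beads, as deposited by the authors. In a separate table the authors gave values on a log2-like scale. Those values ranked the probes of each array exactly as its own signals did (Spearman's rho 1 across probes, which are not independent replicates), lay within 0.0723 of the log2 of the quantile-normalised signals, and were blank where the detection p exceeded 0.01. Whether the authors' scale is log2 or a variance-stabilising transform is not given in the sources used here; the column medians were 7.86, 7.93 and 7.84 for the controls and 7.99, 7.94 and 7.85 for the cKO arrays. GenomeStudio and lumi are named in the submitters' processing notes without versions.

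The deposited signals were background-corrected with the normexp model of limma 3.58.1 (nec, with the detection p standing for the negative controls, since the table listed 0 control probes), given an offset of 16, converted to log2 and quantile-normalised. Of 45281 probes, the 19588 with a detection p under 0.05 on at least 3 arrays were tested, which covered 14002 gene symbols. Gene names were taken from the RefSeq table of assembly GRCm38.p6 through the Entrez identifier (29586 probes) or the accession (2759 probes), and 12936 probes, 3917 of them tested, kept the name in the array file. The brightest tested probe stood for a gene, so counts of list members leave out calls of a gene's other probes.

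Groups were compared with limma's lmFit and eBayes (4 residual and 5.20 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. No block was used. Of 26 gene lists holding 500 genes, 25 were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists, and the sex-linked list was reported as values; 15 listed genes had no symbol match on the array and were not analysed here. A fold given as "at least" applies where a probe was not well above background on any array of the dimmer group: the brighter group's mean was set against the higher, on each array, of the probe's own value and the lowest value among detected probes. The same bound is given for Gbx2 and Nkx2-1, whose probes were above background on only some cKO arrays. Single values were compared with an exact permutation test over the 20 assignments of 3 and 3, in which no p under 0.1 can occur.

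The tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule took Smarcc2; Smarcc1, Pax6, Eomes, Neurog2, Cux1, Tle1, Rest, Tbr1 and Emx1, among others, whatever their values; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out provisional names; and up to 4 members of each list past the threshold by smallest p, or 2 where none passed. Other list members named below were chosen after their values were seen. Some genes that the rule takes are not reported here.

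The procedure was tested on simulated arrays with the 19588 probes. Simulated probes varied independently of each other, and far fewer were changed than the 2358 called in the data. The rates below therefore need not hold for the data. Of 200 probes with a built-in change, 39.0% of those with a log2 change of 0.5 and 100% of those with a log2 change of 1 were recovered, and 4.14% of the calls were unchanged probes. With no built-in change it made 0 probe calls and 0 list calls, and a list shifted by 0.4 (radial glia) was called. In that simulation 2 other lists were called: the Notch pathway, higher, which shares 4 members with it, and intermediate progenitors, lower, which shares 0, a false call (adjusted p = 0.0241).

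Alternatives covered the background correction and its offset, the normalisation, the authors' values, the probe filter, averaging of probes, the variance model, array weights, the replicate number as a block, the Xist level as a covariate, leaving out each array, a fold minimum of 1.5, an estimated correlation and the fry test. With an estimated correlation, camera also tests on the 4 residual degrees of freedom, far fewer than with the preset value. A list call lost there can therefore reflect either change. A chip block was not run because no chip number was used here. Other tools were R 4.3.3, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.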

Results

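Gene expression was measured in the cortex of 3 BAF170 cKO and 3 control embryos at E12.5, when cortical progenitors are starting to produce neurons. BAF170, encoded by Smarcc2, is a scaffold subunit of the BAF (SWI/SNF) chromatin remodelling complex, and Emx1-Cre deletes floxed alleles in progenitors of the dorsal telencephalon. The design asks which cortical transcripts differ when BAF170 is lost. The control embryos carried no Cre, so the Cre allele differed along with the Smarcc2 genotype. Median probe intensity ran from 75.2 to 78.4 over the 6 arrays, 18548 to 20081 of 45281 probes (41.0% to 44.3%) were above background, and a median of 43 or 44 beads stood behind a probe. The number of arrays limits the precision. The labels name a single embryo per array, but nothing else separates biological from technical replicates, so the p-values measure the spread between these arrays and that spread may be technical. Arrays of a group correlated at 0.9945 to 0.995 across probes, and arrays of different groups at 0.986 to 0.987; probes are not independent replicates. The first principal component held 58.5% of the variance and separated the genotypes.

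Smarcc2 was read by 1 probe on chromosome 10 (127918736 to 127918785 in the array file, genome build not given in the sources used here), at position 4261 of its transcript. Its intensity was 851 ± 47.8 in control and 713 ± 44.3 in cKO cortex (SD, n = 3). The log2 change was −0.24 ± 0.09 (SE), a level 15.1% lower, and it did not pass the test (limma adjusted p = 0.124; exact permutation p = 0.1, the smallest that 3 against 3 can give). The part of the gene that is deleted is not given in the sources used here, so a probe lying outside it checks nothing about the labels. Under 4 of the alternatives the change passed, with adjusted p between 0.0227 and 0.0457, and over all alternatives the adjusted p ran from 0.0227 to 0.912.

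In cKO cortex, gene lists of intermediate progenitors and of Pax6-associated cortical genes were higher, and gene lists of the ventral telencephalon and of the diencephalon and midbrain were far lower. Among the 10 genes with the largest rise, Eomes (Tbr2, the T-box factor of intermediate progenitors) was 4.23-fold higher, with a log2 change of 2.08 ± 0.09 (SE, n = 3 per group), Dmrt3, a factor of the medial cortex, was 4.15-fold higher, and Tfap2c, an AP-2 factor of cortical progenitors, was 3.43-fold higher. Rlbp1, a retinaldehyde-binding protein, was at least 10.3-fold higher and Tfap2d, another AP-2 factor, at least 2.37-fold higher. The others were Pde1b, a calcium-dependent phosphodiesterase (log2 change 2.64), Ppp1r1a, an inhibitor of protein phosphatase 1 (2.05), Aldoc, a glycolytic aldolase (2.02), Prr15 (2.02) and Xlr4a (1.66), whose near-identical relatives make its identity uncertain. Among the 10 genes with the largest fall, Gbx2, a factor of the thalamus and the midbrain-hindbrain border, was at least 18.8-fold higher in control than in cKO cortex, where 1 of 3 arrays had it above background (fitted log2 change −4.40 ± 0.09). Nkx2-1, which specifies the medial ganglionic eminence and the hypothalamus, was at least 9.78-fold higher in control and above background on 2 of 3 cKO arrays. Isl1 was 5.20-fold higher in control and Dlx1, a factor of GABAergic neuron development, 4.75-fold. Control levels were at least 4.64-fold higher for Nkx2-2 and at least 5.40-fold higher for Tac1, which encodes the substance P precursor. Pdlim3 (log2 change −3.53, above background on 2 of 3 cKO arrays), the bile acid transporter relative Slc10a4 (−2.34) and Shhrs (−2.31) were also in this group. Adjusted p values of the genes named here lay between 4.81e-08 and 0.000147. The ranks rest on fitted changes, also for probes not above background in a group: by their bounds Tfap2d lies under Neurog2 (2.97-fold) and Nkx2-2 under Dlx2 (4.73-fold), neither of which is in these groups. These folds, bounds included, hold for background-corrected values. Without that correction the fitted fold was 8.15 for Gbx2, 5.22 for Pdlim3, 5.14 for Rlbp1, 4.56 for Nkx2-1, 3.16 for Shhrs, 2.93 for Nkx2-2, 2.91 for Slc10a4, 2.88 for Tac1, 2.36 for Prr15 and 1.98 for Tfap2d, and all of these calls were kept.

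Of 19588 probes tested with limma, 2358 differed at an adjusted p under 0.05, 1095 of them higher and 1263 lower in cKO cortex, corresponding to 927 and 1118 gene symbols, of which 6 had probes in both directions. At least 1.5-fold, 357 probes were higher and 447 lower. At an unadjusted p under 0.05 the number was 5049, and the groups did not overlap for 6076 probes, 31.0% of those tested, where chance gives 10%. Of 786 changed symbols with more than 1 tested probe, 188 had every probe changed the same way. With the Xist level as a covariate 85 probes were called. That covariate, the brightest Xist probe, did not overlap between the groups (log2 intensity 9.20 ± 0.05 in control and 9.01 ± 0.05 in cKO, SD, n = 3), though its change did not pass the test (adjusted p = 0.154).

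**Figure D1:**
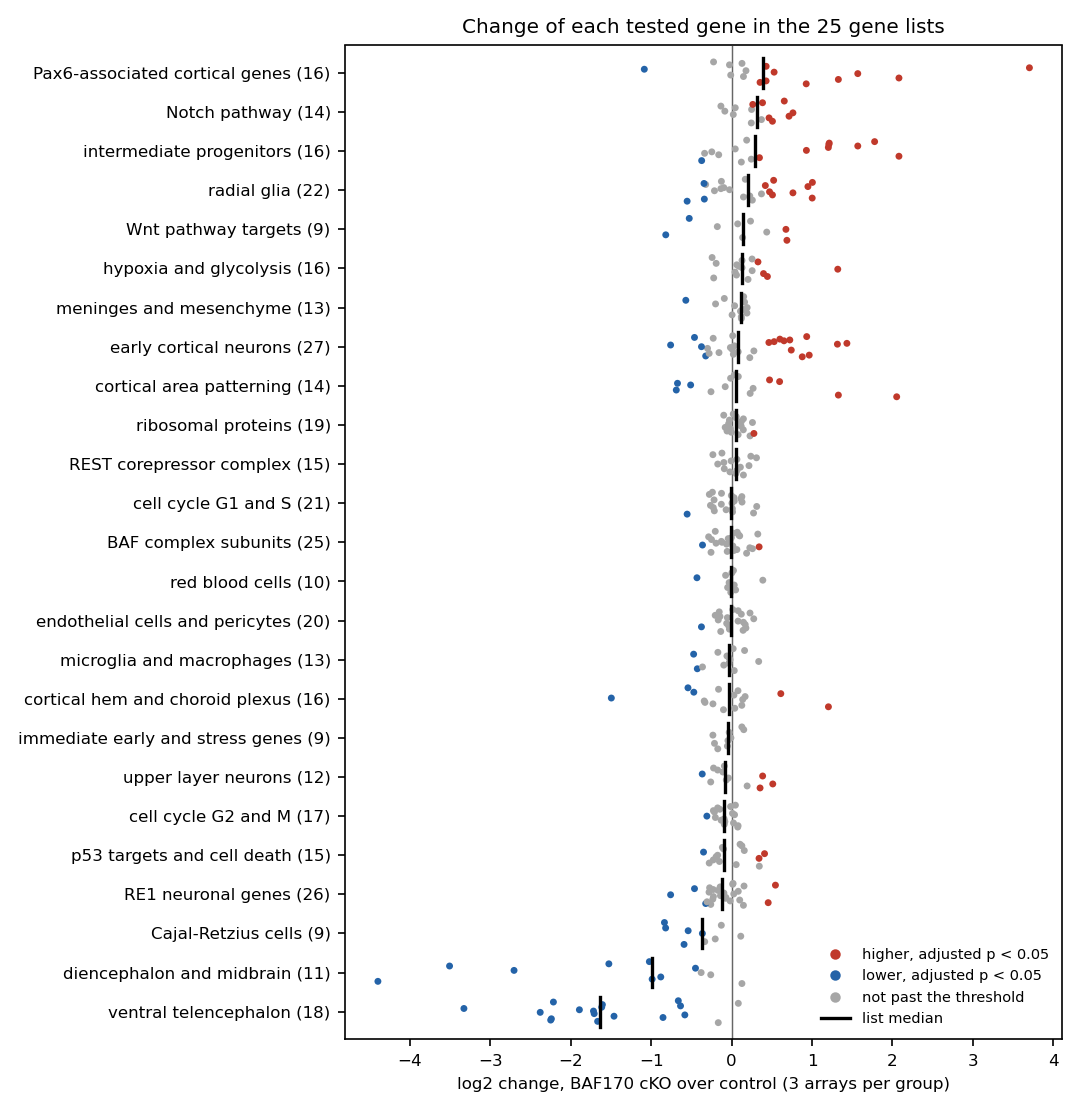
Log2 change of each tested member of 25 gene lists, cKO over control (3 arrays per group), with the number of tested members in brackets. Each point is a gene, red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise, and the black bar is the list median, which runs from −1.64 for ventral telencephalon to 0.39 for Pax6-associated cortical genes.

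Genes of the ventral telencephalon, where GABAergic neurons arise, fell as a group: 16 of 18 tested members were lower and 0 higher, by both the genome-wide adjustment and when adjusted over the list alone. The median log2 change was −1.64 (camera adjusted p = 1.01e-21), and it ran from −1.735 to −1.106 over the alternatives. Besides Nkx2-1, Isl1 and Dlx1, Dlx2 fell by 2.24 ± 0.10 and Lhx8, a factor of cholinergic and GABAergic neurons, fell by 1.89 ± 0.09 (above background on 2 of 3 cKO arrays), whereas Sp8 (0.08) did not pass. Genes of the diencephalon and midbrain fell too, with 8 of 11 lower and 0 higher, 10 lower when adjusted over the list alone, and a median of −0.99, or −0.88 with 4 members at their bound (camera adjusted p = 2.38e-12). This median was −0.64 without background correction and −0.21 when dim probes were kept, and the list was still called (adjusted p = 4.70e-15 and 1.83e-11). Lhx8 and Shh fell less without background correction (by 1.03 and 0.78). Shh, the ventral midline morphogen, fell by 1.53 ± 0.11 (above background on 2 of 3 cKO arrays), alongside Gbx2 and Nkx2-2. Both list calls held with an estimated correlation (adjusted p = 0.0255 for each). The RNA of these regional markers was higher in the control arrays than in the cKO arrays.

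Intermediate progenitor genes rose, with 8 of 16 higher and 1 lower, or 9 and 3 when adjusted over the list alone, and a median of 0.30, or 0.19 with dim probes kept (camera adjusted p = 5.53e-06). Eomes and Tfap2c led the list, followed by Neurog2, the proneural factor of the cortex, which was 2.97-fold higher (log2 change 1.57 ± 0.08), and the somatostatin receptor Sstr2 (1.21 ± 0.08). The cell cycle inhibitor Cdkn1c was lower (−0.37). Among the 7 members not past the genome-wide threshold, Hes6 (−0.34), Insm1 (−0.25) and Gadd45g (−0.16) read below 0. Dll1 (0.25), Tmem158 (0.19) and the brightest Ccnd2 probe (0.12) read above 0. For Ccnd2, 2 of 4 probes were lower and past the threshold (down to −0.83). Genes associated with the transcription factor Pax6 in the cortex rose as well, with 9 of 16 higher and 1 lower, or 9 and 2 when adjusted over the list alone, and a median of 0.39, or 0.18 with dim probes kept and 0.24 with probes averaged per gene (camera adjusted p = 3.40e-06). Rlbp1, Eomes, Neurog2 and Dmrta1 (1.33 ± 0.12, or 0.71 without background correction) led it, so it shares members with the intermediate progenitor list, and Pou3f4 was lower (−1.09). Both calls held with an estimated correlation (adjusted p = 0.0387 for each). Pax6 itself was not tested: its 2 probes were well above background on at most 1 of the 6 arrays. Ventral telencephalon genes had a median change of −1.64 in the same comparison, so a difference in the tissue sampled cannot be told apart from these rises.

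Notch pathway genes, which keep progenitors undifferentiated, rose, with 7 of 14 higher and 0 lower, or 10 and 0 when adjusted over the list alone, and a median of 0.32 (camera adjusted p = 2.33e-05). This call was lost at adjusted p = 0.162 with an estimated correlation, and with the Xist covariate (median 0.18, adjusted p = 0.184). Among its members Hey2 rose by 0.71 ± 0.08, Id4 by 0.76 ± 0.10, the glycosyltransferase Rfng by 0.66 ± 0.11 and Hey1 by 0.47 ± 0.08, while Notch1 (−0.13) did not pass. Radial glia genes rose with 8 of 22 higher and 3 lower, or 11 and 5 when adjusted over the list alone, and a median of 0.20, or 0.08 with dim probes kept (camera adjusted p = 0.0160). That call was lost at adjusted p = 0.176 with an estimated correlation, and with the Xist covariate (adjusted p = 0.0946). The secreted Wnt modulator Sfrp1 (0.95 ± 0.09), the dorsal factor Emx1 (1.003 ± 0.090) and Sox3 (1.01 ± 0.11) were higher, and Ccnd1, Ednrb and Sox2 were lower (−0.55, −0.34 and −0.34), with 1 of 3 Ednrb and 1 of 2 Sox2 probes past the threshold. Diencephalic and midbrain genes had a median change of −0.99 in these samples.

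Early cortical neuron genes went both ways, with 11 of 27 higher and 4 lower, or 13 and 7 when adjusted over the list alone, and a median of 0.08 (camera adjusted p = 0.00400). The call was lost at adjusted p = 0.185 with an estimated correlation, and with the Xist covariate (median 0.05, adjusted p = 0.184). The median was 0.21 without control replicate 2, 0.14 without cKO replicate 2 and 0.17 without cKO replicate 3. The proneural-type factors Neurod2 (1.43 ± 0.07) and Neurod1 (1.32 ± 0.10, or 0.69 without background correction), the adhesion protein Cntn2 (0.97 ± 0.10) and the layer 5 determinant Fezf2 (0.74 ± 0.07) rose, and Tbr1, the factor of deep-layer neurons, was 1.91-fold higher (0.93 ± 0.10, adjusted p = 0.000445). The cytoskeletal genes Nefm (−0.76), Stmn3 (−0.46) and Mapt (−0.37, 1 of 3 probes past the threshold) and the cadherin Celsr3 (−0.32) were lower. Genes of Cajal-Retzius cells, the earliest neurons at the cortical surface, fell with 5 of 9 lower and 0 higher, or 6 and 0 when adjusted over the list alone, and a median of −0.36, or −0.165 with dim probes kept (camera adjusted p = 0.000105). That call was lost at camera adjusted p = 0.0594 with an estimated correlation. The estimate (−0.068) lay under the preset value, so stronger correlation between genes was not the reason. The members that fell were Lhx5 (−0.82 ± 0.08), Zic1 (−0.83 ± 0.10), Calb2 (−0.59 ± 0.08), Lhx1 (−0.54 ± 0.10, 1 of 2 probes past the threshold) and Ebf3 (−0.36, 1 of 2 probes past the threshold), several of which are also expressed in the ventral forebrain and diencephalon; Reln, the secreted signal of these cells, had −0.13 and did not pass. Ventral telencephalon markers were lower in the same arrays (median −1.64).

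Upper layer neuron genes were not shifted (camera adjusted p = 0.919), with 3 of 12 higher and 1 lower, or 3 and 3 when adjusted over the list alone, and a median (−0.08) and mean (0.01) of opposite sign. Plxnd1 (0.39), Kitl (0.51) and Cux1, a factor of upper layer neurons (0.35 ± 0.08, adjusted p = 0.0206), were higher and Pou3f1 (−0.36) was lower. For Cux1 only 1 of 4 tested probes passed and the other probes read below 0, so the average over its probes was −0.05. Leaving out single arrays ended the calls of these 4 genes for 2 (Plxnd1), 4 (Kitl and Cux1) and 5 (Pou3f1) of the 6 arrays, with adjusted p up to 0.0988. The Kitl call also ended in the authors' values (0.21, adjusted p = 0.0551) and with dim probes kept (adjusted p = 0.0544), and the Pou3f1 call with dim probes kept (adjusted p = 0.0513) and with the replicate block (adjusted p = 0.0527). Tle1, a Groucho corepressor, had −0.22 ± 0.08 and did not pass (adjusted p = 0.120); its 5 probes ran from −0.27 to 0.06 and none passed. Diencephalic and midbrain markers were lower in these arrays (median −0.99).

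Cortical area patterning genes did not shift as a list (camera adjusted p = 0.370), with 4 of 14 higher and 3 lower, or 5 and 4 when adjusted over the list alone, and a median of 0.06. Beside Dmrt3 and Dmrta1, the receptor Fgfr3 (0.60 ± 0.10) and Lhx2 (0.47) were higher, and Etv1 (−0.69 ± 0.08, 1 of 3 probes past the threshold), Fgf8 (−0.67) and Fgf17 (−0.51), of the rostral signalling centre, were lower. Cortical hem and choroid plexus genes, at the dorsal midline, did not shift either (camera adjusted p = 0.842), with 2 of 16 higher and 3 lower under both adjustments and a median of −0.04. Dkk3 (1.20 ± 0.12) and the Wnt agonist Rspo3 (0.61 ± 0.10) were higher, and Otx2, a factor of forebrain and midbrain (−1.50 ± 0.09), Ttr, a choroid plexus transcript (−0.47 ± 0.09), and Wnt8b (−0.54) were lower. Wnt pathway target genes had a median of 0.14 (camera adjusted p = 0.508), with 2 of 9 higher and 2 lower, or 4 and 2 when adjusted over the list alone. The feedback inhibitors Nkd1 (0.68 ± 0.09, 1 of 2 probes past the threshold) and Apcdd1 (0.69 ± 0.10) were higher, and the receptor Fzd10 (−0.82 ± 0.09) and the Wnt inhibitor Wif1 (−0.53 ± 0.09) were lower. In these samples, too, ventral telencephalon genes had a median of −1.64.

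Hypoxia and glycolysis genes rose, with 4 of 16 higher and 0 lower, or 6 and 0 when adjusted over the list alone, and a median of 0.13 (camera adjusted p = 0.00609). The call was lost at camera adjusted p = 0.122 with an estimated correlation. The estimate (−0.010) lay under the preset value, so stronger correlation between genes was not the reason. The list call was also lost with the Xist covariate (adjusted p = 0.371). Ndrg1 (1.32 ± 0.11) and Ddit4 (0.45 ± 0.07), both stress-responsive, and the glycolytic enzymes Pgk1 (0.33 ± 0.08, 1 of 2 probes past the threshold) and Eno1 (0.40 ± 0.09) were higher. The Pgk1 call ended without 5 of the 6 arrays and the Eno1 call without 4, with adjusted p up to 0.0804, and the Pgk1 call ended with probes averaged (0.21, adjusted p = 0.150) and with the replicate block (adjusted p = 0.0561). Immediate early and stress genes, read as a sign of tissue handling, had 0 of 9 members past the threshold by limma in either direction, also when adjusted over the list alone, and 1 (Dusp1, −0.21) at an unadjusted p under 0.05 (camera adjusted p = 0.810). Jun had 0.15. Genes of p53 and cell death had 2 of 15 higher and 1 lower under both adjustments (camera adjusted p = 0.919), namely Phlda3 (0.41, 1 of 2 probes past the threshold), Eda2r (0.34, above background on 1 of 3 control arrays) and Plk2 (−0.35). Eda2r and Plk2 did not pass without any 1 of the 6 arrays, nor did Phlda3 without 4 of them (adjusted p up to 0.136). Their calls ended under other settings too, among them Eda2r without background correction (0.15), Phlda3 with probes averaged (0.26, adjusted p = 0.0728) and Plk2 with dim probes kept (adjusted p = 0.0789). Cell cycle genes were counted by their brightest probe. Ccnd1, a G1 cyclin (−0.55 ± 0.08), was the 1 of 21 G1 and S members that was lower, under both adjustments, and 0 were higher (camera adjusted p = 0.508). Other probes, 1 of 2 for Cdc6 (−0.44) and 1 of 4 for Mcm6, were also lower and past the threshold. Cenpf, a kinetochore protein (−0.31, 1 of 3 probes past the threshold), was the 1 of 17 G2 and M members that was lower (camera adjusted p = 0.234 for the list). When adjusted over the list alone, 0 members were lower. The Cenpf call ended without 5 of the 6 arrays, with adjusted p up to 0.129, and with probes averaged (−0.22, adjusted p = 0.0906) among other settings. For Top2a, 2 of 3 probes, not its brightest (−0.17), were lower and past the threshold (down to −0.57). The ventral telencephalon median of −1.64 stands beside these groups as well.

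Subunits of the BAF complex, the complex that contains BAF170, did not shift (camera adjusted p = 0.978), with 1 of 25 higher and 1 lower under both adjustments. For Actl6a the brightest probe read 0.19 and did not pass, and its other probe was lower (−0.35, limma adjusted p = 0.0156). Bcl7a was higher (0.34 ± 0.08) and Bcl7c lower (−0.36 ± 0.08, 1 of 3 probes past the threshold, with the other probes above 0). The Bcl7a call ended without 5 of the 6 arrays, with adjusted p up to 0.0839, and the Bcl7c call without cKO replicate 3 (−0.34, adjusted p = 0.0545). The Bcl7a call also ended with the replicate block (adjusted p = 0.0581) and the Bcl7c call with probes averaged (−0.05, adjusted p = 0.730). Smarcc1, which encodes the paralogous scaffold BAF155, had −0.28 ± 0.10 and did not pass (adjusted p = 0.0978), and its other probe read 0.22 (adjusted p = 0.245), so the average over its probes was −0.03. Its change passed under 4 alternatives, over a range of adjusted p from 0.0119 to 0.798. Members of the REST corepressor complex, which silences neuronal genes outside neurons, had 0 of 15 past the threshold by limma, also when adjusted over the list alone, and a median of 0.05 (camera adjusted p = 0.787). That count takes the brightest probes. For Rcor1 the brightest probe read 0.07, and its other probe was lower (−0.40, limma adjusted p = 0.0489). Rcor2 (0.31) and the demethylase Kdm1a (0.22) had the smallest p values, and 4 members (also Sin3a, −0.23, and Rcor3, 0.24) lay at an unadjusted p under 0.05. Rest itself was not tested, since its 1 probe was well above background on 0 arrays. Neuronal genes with RE1 sites, the elements REST binds, did not shift (camera adjusted p = 0.154), with 2 of 26 higher and 3 lower, or 2 and 6 when adjusted over the list alone. Syt4 (0.55 ± 0.09) and Chga (0.46 ± 0.08, 2 of 3 probes past the threshold), both of secretory vesicles, were higher, and the lower ones were Nefm, Stmn3 and Celsr3. Genes of the diencephalon and midbrain had a median of −0.99 beside these groups.

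Markers of other cell types that a cortical sample can hold did not shift as lists. For endothelial cells and pericytes 0 of 20 were higher and 1 lower by their brightest probe (camera adjusted p = 0.919), with a median (−0.01) and mean (0.005) of opposite sign. That gene, Egfl7, had 1 of 3 probes lower (−0.37 ± 0.07, adjusted p = 0.0107) and 1 higher (0.33 ± 0.09, adjusted p = 0.0387), and the average over its probes was −0.04. For microglia and macrophages 0 of 13 were higher and 2 lower (camera adjusted p = 0.444), Aif1 (−0.43 ± 0.09, 1 of 2 probes past the threshold) and Lyz2, at least 1.27-fold higher in control. The Aif1 call ended without control replicate 1 (−0.39, adjusted p = 0.0534) and in the authors' values (−0.18, adjusted p = 0.0856), and the Lyz2 call without cKO replicates 1 and 3 (adjusted p up to 0.0692) and with the replicate block (adjusted p = 0.0531). For meninges and mesenchyme 0 of 13 were higher and 1 lower (Ogn, −0.57 ± 0.09; camera adjusted p = 0.535), and for red blood cells 0 of 10 were higher and 1 lower, the embryonic globin Hbb-bh1 (−0.43 ± 0.09; camera adjusted p = 0.921). When adjusted over the list alone these counts were the same, except that 1 red blood cell gene was also higher. Probes other than the brightest were past the threshold in both directions. For Hbb-b1, 3 of 10 probes were lower (all 10 ran from −0.58 to −0.03), and for Col1a1 1 of 2 was lower (−0.63). For Lum 1 of 2 probes was higher, and for Cxcl12 2 of 3. Ribosomal protein genes had 1 of 19 higher, Rpl19 (0.28 ± 0.07), whose call ended without any 1 of the 6 arrays (adjusted p up to 0.111), after median scaling (adjusted p = 0.0655) and with the replicate block (adjusted p = 0.0791), and 0 when adjusted over the list alone; the list was not shifted (camera adjusted p = 0.154) but was called after median scaling and after cyclic loess (adjusted p = 0.00281 and 0.0216). Ventral telencephalon genes had a median of −1.64 beside these markers.

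Sex-linked transcripts were read together on every array. The brightest Xist probe, for the RNA that silences an X chromosome in females, had an intensity of 650 ± 56.4 in control and 561 ± 6.41 in cKO cortex (SD, n = 3), and all 4 Xist probes were above background on all 6 arrays. None of them passed the test (adjusted p between 0.115 and 0.370): 2 read lower in cKO cortex (−0.19 and −0.15) and 2 higher (0.44, from 252 to 315, and 0.12, from 165 to 172). The Y-linked Ddx3y had 625 ± 30.6 and 488 ± 14.1 at its 1 detected probe of 3 (log2 change −0.35, adjusted p = 0.0334), Eif2s3y 251 ± 19.0 and 233 ± 15.8, Kdm5d 143 ± 10.04 and 136 ± 13.0, and Uty 95.3 ± 9.22 and 93.0 ± 9.22 at its 1 detected probe of 4. Of 5 sex-linked genes 1 was lower, also when adjusted over the list alone, and 0 were higher.

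**Figure D2:**
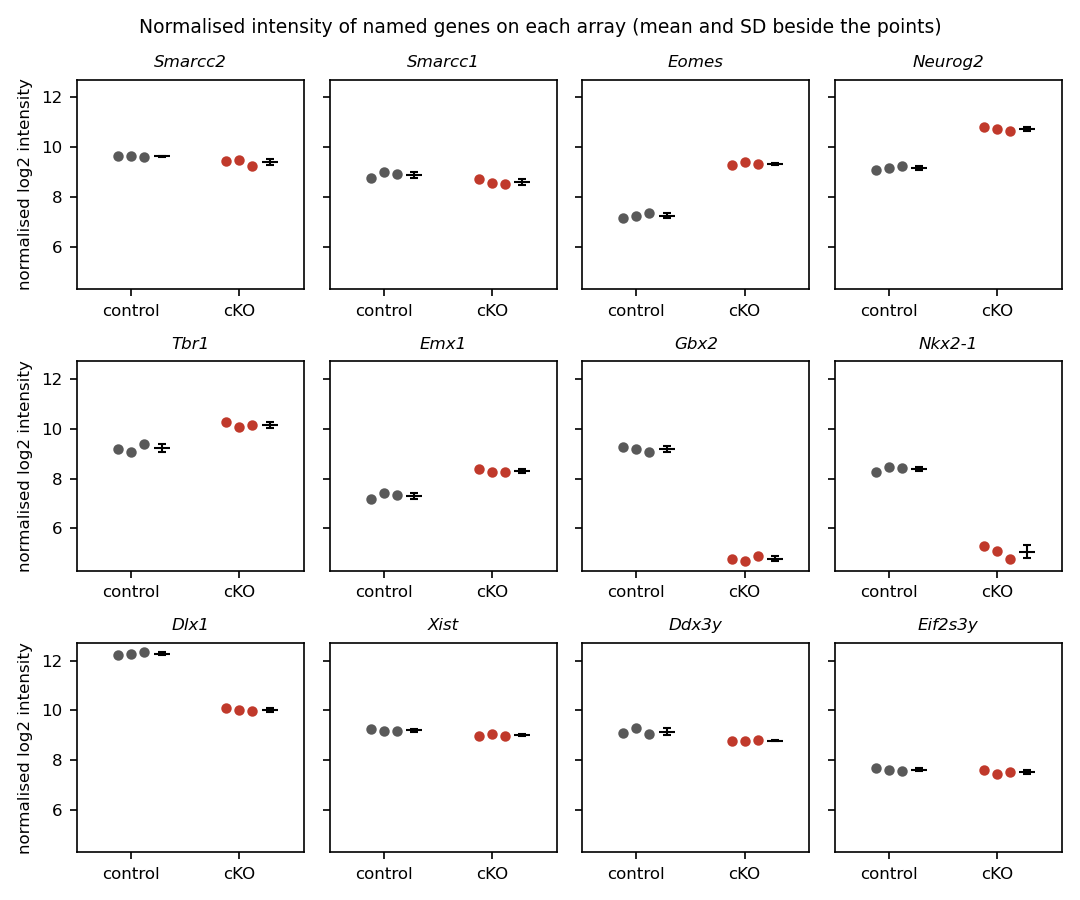
Normalised log2 intensity of 12 genes on each of the 3 control (grey) and 3 cKO (red) arrays, with the group mean and SD as a bar beside the points, on a shared axis. Eomes, Neurog2, Tbr1 and Emx1 lie higher in cKO, Gbx2, Nkx2-1 and Dlx1 lie lower, Smarcc2 changes by −0.24, and Xist and the Y-linked Ddx3y and Eif2s3y are present in all 6 arrays.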

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

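All alternatives in this part were set before the data were examined. The 2358 changed probes compare with counts within 1.5 times under 11 settings, from 1938 probes with dim probes kept to 3278 with trend and robust. The 11 include probes averaged per gene, where 1854 gene symbols were called, beside 2039 symbols with a changed probe in the main fit. When single arrays were left out, 1607 to 1740 probes were called. Requiring at least 1.5-fold left 804 probes by its construction. With the Xist covariate 85 probes and 5 lists were called, with Notch pathway, early cortical neurons, hypoxia and glycolysis, and radial glia lost, and 52 of the 77 named genes that were called lost their call. The brightest Xist probe did not overlap between the genotypes, which by construction widens the standard error 2.52-fold; of the 52 estimates 31 also became smaller and 21 larger (median ratio 0.977), for which the cause was not tested. The split of the 6 arrays by genotype gave 2358 probes and the highest other of the 10 splits gave 0 (1 split reached the real count, its own), but 10 splits are too few for a share under 0.05.

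The Smarcc2 change kept its direction throughout and passed under 4 settings: −0.22 with no background correction (adjusted p = 0.0316), −0.23 with an offset of 50 (0.0457), −0.22 in the authors' values (0.0253) and −0.24 with trend and robust (0.0227). Its range over left-out arrays was −0.27 to −0.16, and the cause was not tested. Of the 25 lists, 9 were called. With an estimated correlation, where camera tests on the 4 residual degrees of freedom, 4 remained. By fry, which asks only whether genes move one way on balance, 15 passed. Median scaling and cyclic loess each gave 10 lists (ribosomal proteins added), and each left-out array 9. In the authors' values 24 lists could be tested and 8 were called; the list of the diencephalon and midbrain was the one left untested, and no call was lost. Keeping dim probes left every list call in place, though several medians became smaller. Without background correction 15 named genes had folds over 1.5 times smaller, and with an offset of 50, 12; all kept their calls. On the log2 scale 31 of the 77 called named genes became over 1.5 times smaller under at least 1 setting other than left-out arrays and the Xist covariate, 22 of them without background correction and 13 in the authors' values, and 0 became larger; 14 lost their call in at least 1 of these settings.

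Cux1 reversed to −0.0519 when its probes were averaged, because its 4 probes disagree, and Lyz2 reversed to 0.0296 with the Xist covariate, for which the cause was not tested. Smarcc1, Tle1, Rcor2 and Kdm1a passed under the same 4 settings as Smarcc2, and Dusp1 under 3 of them. Of 83 named genes, 15 lost their call in at least 1 left-out array. No shared variation by replicate number was seen: deviations of same-numbered arrays correlated at 0.018, −0.002 and 0.047. A pairing of embryos could leave no trace here if the spread within groups is technical. The fit with the replicate block called 1957 probes, 1847 of them shared, and 9 lists. A chip block was not run. Probes near background, such as those of Pax6 and Rest, carried too little signal to be tested.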

Other observations

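The enrichment tests, the comparison of Eomes with other cortical genes, the tests on the authors' values, on the normalisation and on cortical cells, and those on the sex-linked signals were chosen after the results were seen. The further list of regional genes and the test of within-group spread were written before their results, except that the value of 1 list member, Dlk1, was already known.

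Genes were also grouped by the process terms of the array annotation (371 terms of 10 to 500 genes, over 7219 annotated genes, hypergeometric test with adjustment over the terms). That test treats genes as independent, which they are not, so its p-values do not measure the spread between arrays. The genes named in this paragraph were chosen after their values were seen. Among genes higher in cKO cortex, 2 terms were enriched, and the broader, development of the organism, was enriched in both directions: of 409 genes 50 were higher (adjusted p = 0.000529) and 63 lower (adjusted p = 6.32e-09). Wnt signalling held 15 higher genes of 86 against 5.27 by chance (adjusted p = 0.0362), among them Wnt7b (0.90 ± 0.09 log2), a Wnt ligand of the cortex, Sfrp1 (0.95) and the receptor Fzd1 (0.72), and it held 12 lower genes as well (adjusted p = 0.134). Among genes lower in cKO cortex, 12 terms were enriched, the strongest being regulation of transcription with 51 lower genes of 228 against 14.7 by chance (adjusted p = 4.09e-13) and 17 higher. Axon guidance held 14 lower genes of 51 against 3.29 by chance (adjusted p = 0.000313), including the guidance receptors Robo3 (−0.84) and Ephb1 (−0.77) and the ligand Efna5 (−0.88), and 8 higher genes (adjusted p = 0.306), among them Neurog2 and Tbr1. Sodium ion transport held 10 of 44 against 2.84 (adjusted p = 0.0143), with Atp1b1 (−0.93) and Scn1a (−0.57), and it held 4 higher genes, among them the vesicular glutamate transporter Slc17a7, of excitatory neurons (1.52), while Slc17a8 was lower (−1.09). The lower terms also hold the regional factors Gbx2, Nkx2-1 and Shh, and ventral telencephalon genes had a median of −1.64 in the same arrays.

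Of 29 tested genes of the ventral telencephalon and diencephalon lists, 24 were lower in cKO cortex. Background correction and quantile normalisation are argued against as the source, since all 12 of these genes with a value in the authors' uncorrected table (100%) were called lower there too, as were all 24 without background correction, after median scaling and after cyclic loess (100%), and 23 with an offset of 50. If more non-cortical tissue in the control samples were the source, a further list of striatal, hypothalamic and thalamic genes was to show a median under −0.3 with at least 75% of members below 0: its 27 tested genes of 44 had a median of −0.39 (95% of 10000 matched random lists lay between −0.10 and 0.08), with 14 called lower, 1 called higher and 74.1% below 0, which misses the bound (−0.35 and 73.1% without Dlk1). The striatal members of that list did not fall alike. Foxp2 (−0.83) and Rxrg (−0.78) were called lower, Ppp1r1b (0.81) was called higher, and the others lay between −0.10 and 0.17 without passing. The remaining lower calls were of hypothalamic and thalamic members. Some striatal members not called, such as Penk (mean log2 5.05 in control) and Ebf4 (5.19), lay near the lowest detected values (4.89 to 5.02). Such probes had little room to fall, though Rxrg was called lower from 5.33. The share below 0 counts dim probes too, among them Lhx3 (5.18) and Epha8 (5.19), whose changes were above 0, and Foxb1 (5.15), whose change was below 0. Of the list's members, Foxp1, Foxp2, Zfp521 and Pcdh19 are made in the cortex as well. Tissue caught in the dissections and lower expression inside cortical cells both stay open and cannot be told apart, since no sample is known to hold cortex only.

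Eomes was higher in cKO cortex by 2.08 on the log2 scale. Dilution of cortical RNA by other tissue in the controls would raise alike those cortical genes that the other tissue does not make. Eomes rose by 1.08 ± 0.09 (SE) more than Emx1 (95% interval 0.84 to 1.32). The point estimate of that margin ran from 0.95 to 1.09 over 6 value settings. Eomes rose by 1.15 more than Tbr1 and by 1.34 more than Fezf2. The margins were smaller over Neurod2 (0.65, and 0.35 in the authors' values) and Neurog2 (0.51 and 0.26). Under dilution, a comparison gene that the other tissue also makes would rise less, and whether these genes are made there was not tested. The margins therefore cannot decide whether dilution is the whole cause. The Cre allele is driven from Emx1 and was carried only by cKO embryos, which could affect Emx1 itself but not the other 4 genes in the same way. More Eomes RNA per cortical cell after loss of BAF170 is a hypothesis that stays open, as does dilution as a part or the whole of the rise. No samples of matched dissection were analysed here.

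Arrays of a group were close to each other, and Xist was detected together with the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty on 6 of 6 arrays. Single embryos of both sexes within a group are argued against, since the brightest Xist and Ddx3y probes ranged by at most 0.26 (log2) within a group, and every Xist and Y-linked probe detected on all arrays by at most 0.55. RNA pooled from embryos of both sexes may explain the joint signal, which the labels' single embryos do not provide for, but the 4 Y-linked genes have X-linked homologues, so cross-hybridisation stays open. One RNA measured repeatedly within a group also stays open: arrays of a group differed by 1.19 to 1.30 times the bead error, and tissue and blood genes varied within groups at the 71.8th percentile of matched random lists. No biological explanation was tested.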
